A study of Mus musculus with 2 samples.

How the data were processed

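Tumour cells of 2 mice were measured by single-cell RNA sequencing, 1 library per group. The groups were taken from the labels: MC38 cells transduced with SPP1 or with a vector, both treated with an antibody against PD-1. The deposited values were raw UMI counts per gene and cell barcode, with no normalization, which was checked on the values. Cell Ranger 2.1.1 and the genome build GRCm39 are named per the submitters' processing notes. The cell barcodes were 20 bases long in both libraries, and the library chemistry was not settled from the sources used here. The annotation release, the way in which cells were called and any earlier removal of doublets or free RNA are not given in the sources used here. Each table held 56941 genes, of which 297 symbols named more than 1 gene. Such symbols were told apart by Ensembl identifier, and Nrg1 stands for ENSMUSG00000062991.

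The library labelled vector held 14317 barcodes, 164247003 UMIs and a median of 10277 UMIs and 3507 genes per barcode. The library labelled SPP1 held 14029, 164599332, 10218 and 3550. The lowest barcode held 502 UMIs in both. Cells with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept, which were 14243 and 13956. Doublets were predicted per library by Scrublet's method, written anew, with 2 simulated doublets per cell, an expected rate of 0.06 and Otsu's threshold on the simulated scores. They were removed: 279 (1.96%) in the library labelled vector and 407 (2.92%) in the library labelled SPP1, which left 13964 and 13549 cells.

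Counts were scaled to 10000 per cell, logged, and reduced to 30 principal components of 2000 variable genes with values limited to 10. Cells of both libraries were joined by their 20 nearest neighbours, weighted by shared neighbours, and clustered by the Leiden method at resolution 1.0 with seed 0 and no batch integration. Clusters were named from 26 marker lists fixed before the data were examined. A marker was raised when it had at least 10 CPM and a log2 ratio of at least 1 over the other cells, and a list needed at least 3 raised markers. Several further thresholds were set after the data had been examined. These were 50% of the list raised, a mean log2 ratio of at least 2, a low-UMI set for clusters without a name whose median lay under 0.5 of the library's median, and a mixed set for clusters at or above 0.25 of the compartment's level of Hmga2, Sox9, Tafa1 and Hoxa9. Named clusters under 0.5 kept their name. Under 1/3 of the median, however, a name also needed a marker of the same kind of cell among the cluster's 10 top genes. T and NK-like, phagocyte and dendritic, and stromal cells were clustered again on 15 or 20 components. There a name did not need the mean log2 ratio, and was dropped where a list of another kind of cell also passed. No cluster passed the tumour marker list, so the planned tumour-like class was replaced by the large compartment without a name.

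For each class, UMIs were summed per library and given as CPM of the class. With 1 library per group no test across samples was possible, and cells were not used as replicates. Shares have exact binomial intervals, CPM exact Poisson intervals and log2 ratios exact conditional binomial intervals, all at 95%. Share ratios have log intervals. These cover counting error only. As a measure of spread between the libraries, the median size of the log2 ratio among genes with at least 1000 UMIs was 0.114 in the compartment (10761 genes), 0.132 in macrophage/monocyte-like cells (2329 genes) and 0.151 in T and NK-like cells (160 genes). Detection was compared in cells thinned to 1000 UMIs, with shallower cells left out. A count of 0 was bounded with a floor of 3 counts.

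The rule for named genes was fixed before the data were examined, as were the lists, the comparisons and the first set of other settings. Within a class of at least 100 cells per library, it took genes with at least 100 UMIs, at least 50 CPM in a library and an interval that excluded a 1.5-fold ratio. It named up to 12 each way in the compartment and in macrophage/monocyte-like cells and up to 8 each way in T and NK-like cells. Mitochondrial, ribosomal, haemoglobin, clone-named, receptor-segment and Y-linked genes, Xist and Tsix were left out, as were genes whose level lay under 10% of that in another class in both libraries. Other X-linked genes were kept. Spp1, Cd44, 5 integrin genes, Cd274 and Pdcd1 were always named, with up to 4 members of each list, of which the text gives some. Single values of a few list members are not reported here. The 12 each way planned for tumour-like cells were used for the compartment.

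The 26 fixed gene lists were read as the median log2 ratio of members with at least 20 UMIs in the class. Intervals came from 1000 Poisson draws, and percentiles from 10000 random lists matched on expression among 100 neighbours on each side, as a description of these libraries. Of 78 pairs of list and class computed, 3 had fewer than 3 members and 48 are described, 18 in the compartment, 17 in macrophage/monocyte-like cells and 13 in T and NK-like cells. The restriction to lists that suit the class was made after the values had been seen, although all pairs had been planned, and the other 27 are given among the other observations. Ctgf was not measured under that symbol, and Aldoa named more than 1 gene and was not used. Regulatory T-like cells replaced all T and NK-like cells as the reference for free Spp1 RNA, since NK-like cells carried Spp1.

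Genes were assigned to chromosomes by Ensembl identifier in GENCODE M21, which is on another build, so no coordinates are given. Of 7506 genes compared, 7478 had a chromosome. The ratio, naming and list functions were tested on simulated data with 200 altered genes per class. Both libraries were drawn as Poisson counts from a shared profile, which is the model the intervals assume. Differences between mice or in cluster make-up were not simulated, so the run checks the functions only. The naming rule was run there without its limit on number and without the comparison with other classes. At simulated ratios of 2, 4, 0.5 and 0.25, the rule called 50, 50, 49 and 46 of 50 genes in the compartment, with none of 3560 unaltered genes called and 95.1% of intervals covering the truth. In macrophage/monocyte-like cells it called 49, 50, 49 and 49 of 50, none of 3327, with 95.0% covered. In T and NK-like cells it called 28, 50, 22 and 38 of 50, none of 2058, with 95.8% covered.

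Other settings chosen before the data were examined were a stricter filter (1000 genes, 10% mitochondrial), a looser filter (200 genes, 25%), doublets kept, resolutions 0.5 and 2.0, clustering of each library on its own, thinning to 2000 UMIs before clustering, other denominators, TMM and median-of-ratios scaling, means over cells, thinning to 1000 UMIs, list minimums of 1 and 100 UMIs and unthinned cycling shares. Settings added after the data had been examined were another seed, leaving out clusters 4 and 12, leaving out the 3 highest cells per gene, and clustering T and NK-like cells without the genes that differed 1.5-fold. Macrophage/monocyte-like clusters were formed without such genes in the reported values, also a choice made after the data had been examined. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.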

Results

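Single-cell RNA libraries were made from subcutaneous tumours grown from MC38 cells, a mouse line that the labels call colon adenocarcinoma. The cells had been transduced with a lentivirus carrying either SPP1 or an empty vector, and the labels state that SPP1 protein was seen by Western blot. SPP1, or osteopontin, is a secreted glycoprotein that binds the receptor CD44 and several integrins. Mice of both groups received an antibody against PD-1, an inhibitory receptor of T cells, at 10 mg/kg 2 times per week for 2 weeks, starting on day 7. The tumour of 1 mouse per group was sequenced, so every difference below is between 2 libraries, has no replicate check and was not tested across animals. The intervals are 95% intervals that cover counting error only. The library labelled vector held 14317 cell barcodes and 164247003 unique molecular identifiers (UMIs), with a median of 10277 UMIs per barcode. The library labelled SPP1 held 14029 barcodes and 164599332 UMIs, with a median of 10218. After filtering and removal of predicted doublets, 13964 and 13549 cells were kept.

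Spp1 itself was not higher in the library labelled SPP1 over all kept cells or in the largest class taken whole. Over all kept cells it stood at 285 CPM, the usual scaling of UMIs to a fixed total, in the library labelled vector and 250 in the library labelled SPP1, a log2 ratio of -0.19 (-0.21 to -0.17), which turned to 0.10 without the clusters 4 and 12 named below. Of the 45039 and 38913 Spp1 UMIs behind that ratio, 6482 and 1719 lay in only 40 and 42 fibroblast-like cells. In the large compartment of proliferating, matrix-producing cells described in the next paragraph, Spp1 was 135 and 128 CPM, a log2 ratio of -0.07 (-0.10 to -0.04). That ratio was 0.21 (0.18 to 0.24) without clusters 4 and 12, which came almost wholly from the library labelled SPP1 and held little Spp1, and 0.00 in cells thinned to a fixed number of UMIs. The clusters left still differed in make-up. Cluster 0, also low in Spp1 at 41.8 and 55.3 CPM, held 2706 cells of the library labelled vector and 1572 of the other. Within single clusters of the compartment, Spp1 was higher with an interval above 0 in clusters 0 (0.40), 2 (0.45), 3 (0.24), 8 (0.40) and 15 (0.31), and lower with an interval below 0 in cluster 19 (-0.80). In clusters 8, 15 and 19, the 3 highest cells held 12.9%, 12.9% and 23.9% of the UMIs in the library labelled vector and 33.1%, 39.5% and 39.4% in the other. The share of cells with an Spp1 UMI was 33.8% and 35.2% in cluster 8 and 36.1% and 31.5% in cluster 15. In thinned cells these shares were 9.68% and 8.81%, and 6.75% and 8.47%. Macrophage/monocyte-like cells carried more Spp1, at 2279 and 2633 CPM (log2 ratio 0.21, 0.18 to 0.24). Fibroblast-like cells held 14021 and 4172 CPM (-1.75, -1.83 to -1.67) in 40 and 42 cells, of which the 3 highest held 42.9% and 59.0% of the UMIs. Without these cells the ratio was -2.28. T and NK-like cells held 1158 and 3402 CPM (1.55, 1.44 to 1.67), but 3 cells of the library labelled SPP1 held 82.3% of its Spp1 UMIs there, and the ratio was 0.07 without the 3 highest cells of each library. Within that class, NK-like cells held 2454 and 9007 CPM, CD8 T-like cells 748 and 317 CPM, and regulatory T-like cells 31.6 and 93.9 CPM from 3 UMIs in each library. The 3 highest cells held 57.3% and 87.2% of the NK-like UMIs and 72.3% and 45.0% of the CD8 T-like ones. An Spp1 UMI was found in 59.5% and 48.5% of NK-like cells and in 38.1% and 36.8% of CD8 T-like cells. Dendritic cell-like cells held 138 and 66.9 CPM (-1.05, -2.16 to -0.07) from 42 and 11 UMIs, of which the 3 highest cells held 52.4% and 81.8%. The ratio was -2.43 without the 3 highest cells of each library, on the few UMIs left. Endothelial-like cells held 23.3 and 31.0 CPM from 3 and 5 UMIs. Since Spp1 over all kept cells did not separate the libraries in the labelled direction, the libraries are named by their labels throughout. A construct that carries only a coding sequence, or that of another species, need not be counted at mouse Spp1.

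After thinning each cell to 1000 UMIs, 9.58% of compartment cells in the library labelled vector and 8.82% in the library labelled SPP1 had an Spp1 UMI (unthinned 42.1% and 39.7%, with 22 and 31 shallower cells left out). In macrophage/monocyte-like cells the thinned shares were 52.2% and 56.2% (unthinned 75.2% and 76.5%, with 60 and 66 left out). Among regulatory T-like cells, they were 6.67% (0.818 to 22.1%) and 8.33% (0.211 to 38.5%), at median depths of 2174 and 2044 UMIs against 12478 and 12108 in the compartment. These cells served as a reference for free RNA on the premise that they lack Spp1, which was not tested. The compartment's share lay within the intervals of the regulatory T-like cells. These rest on 30 and 12 thinned cells and are too wide to tell compartment Spp1 from free RNA. By CPM, the compartment's 135 in the library labelled vector lay above the regulatory T-like 31.6 (6.51 to 92.2). In the library labelled SPP1 its 128 lay within the interval of 19.4 to 274. The compartment's share was not uniform, however, and ran in the library labelled SPP1 from 2.83% (2.09 to 3.75%) in cluster 4 to 18.1% (15.1 to 21.4%) in cluster 7.

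**Figure D1:**
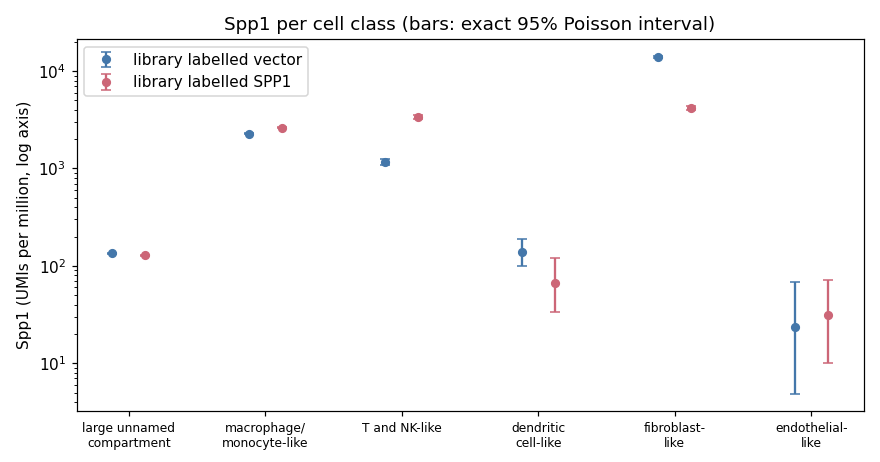
Spp1 in 6 cell classes, in CPM on a log axis; points are the library labelled vector and the library labelled SPP1, and bars are exact 95% Poisson intervals. The compartment lies at 135 and 128 CPM, and the widest gap between the libraries is in fibroblast-like cells, at 14021 and 4172 CPM.

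The first comparison asked which cell populations of the tumour differed in proportion. The compartment without a name was the largest class, at 72.9% (72.1 to 73.6%) of kept cells in the library labelled vector and 73.9% (73.1 to 74.6%) in the library labelled SPP1. It carried collagen (Col3a1, 6430 and 6987 CPM), the transcription factors Sox9 (834 and 869 CPM) and Prrx1 (366 and 328 CPM) and the chromatin protein gene Hmga2 (847 and 848 CPM), and lacked the keratin Krt8 (0.154 and 0.208 CPM) that was among the markers fixed for tumour cells. It therefore kept no cell type name. T and NK-like and dendritic cell-like cells made up a smaller part of all kept cells in the library labelled SPP1. T and NK-like cells made up 1.36% (190 cells) and 0.878% (119 cells), a log2 ratio of -0.63 (-0.96 to -0.30). Dendritic cell-like cells, which present antigen to T cells, made up 0.301% (42 cells) and 0.170% (23 cells), a log2 ratio of -0.83 (-1.56 to -0.09). Macrophage/monocyte-like cells made up 6.65% (929 cells) and 5.56% (753 cells), a log2 ratio of -0.26 (-0.39 to -0.13). Among immune cells alone, macrophage/monocyte-like cells were instead 80.0% and 84.1%, a log2 ratio of 0.07 (0.01 to 0.13), T and NK-like cells 16.4% and 13.3% (-0.30, -0.61 to 0.01) and dendritic cell-like cells 3.62% and 2.57% (-0.49, -1.22 to 0.23). Under the stricter cell filter the dendritic ratio of all kept cells was -0.65 (-1.38 to 0.09). Fibroblast-like cells (40 and 42 cells; 0.11, -0.51 to 0.74), endothelial-like cells (18 and 22 cells; 0.33, -0.57 to 1.23) and pericyte or smooth muscle-like cells (4 and 7 cells) were few, and no difference was detectable at these numbers. Cells of low UMI content without a name made up 16.1% and 16.9% of kept cells. Clusters that mixed markers of the compartment with those of another class made up 2.26% and 2.15%. Both sets were kept out of the named classes by thresholds set after the data had been examined. Cluster 13, a low-UMI cluster, held 69 cells of the library labelled vector and 570 of the library labelled SPP1.

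**Figure D2:**
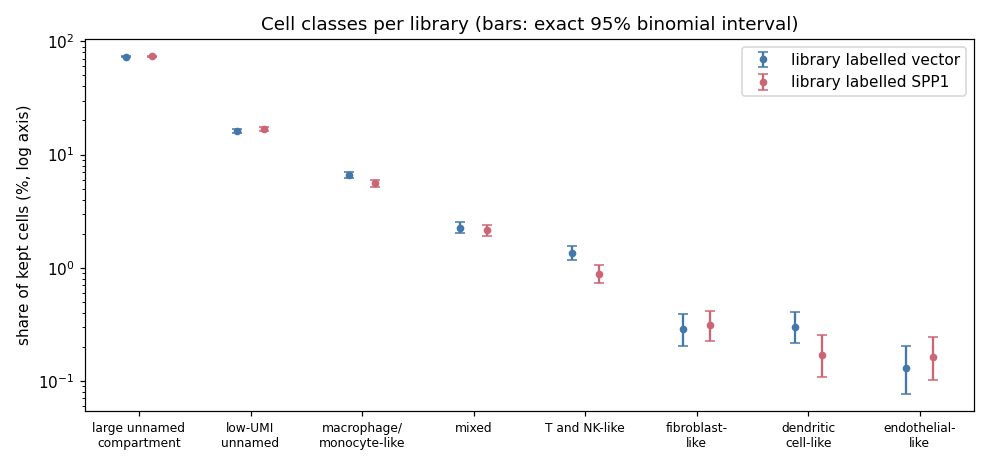
Share of kept cells in 8 classes, in percent on a log axis, for the library labelled vector and the library labelled SPP1, with exact 95% binomial intervals as bars. T and NK-like cells stand at 1.36% and 0.878%, and dendritic cell-like cells at 0.301% and 0.170%.

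The make-up of the T and NK-like class was compared because both groups had received the PD-1 antibody. CD8 T-like cells formed 44.2% (37.0 to 51.6%) of the class in the library labelled vector and 47.9% (38.7 to 57.2%) in the library labelled SPP1, from 84 and 57 cells. NK-like cells formed 22.1% and 27.7%, from 42 and 33 cells (log2 ratio 0.33, -0.24 to 0.90). Regulatory T-like cells, which restrain other T cells, formed 16.8% (11.8 to 22.9%) and 10.9% (5.95 to 18.0%), from 32 and 13 cells (-0.62, -1.49 to 0.24). There were 2.63 CD8 T-like cells per regulatory T-like cell in the library labelled vector and 4.38 in the library labelled SPP1, the latter from 13 regulatory T-like cells. When the class was clustered without the 246 genes that differed between the libraries, regulatory T-like cells numbered 33 and 19, a log2 ratio of -0.12. CD8 T-like cells then numbered 67 and 47, so their number per regulatory T-like cell differed less between the libraries. Cells without a sub-class name formed 16.8% and 13.4%. No difference in these shares of the class was detectable at this number of cells. As a share of all kept cells, each sub-class was lower in the library labelled SPP1, as was the whole class (-0.63). CD8 T-like cells were at a log2 ratio of -0.52 (-0.9999 to -0.0319) and NK-like cells at -0.30 (-0.96 to 0.35). Cells without a sub-class name were at -0.96 (-1.82 to -0.09). Regulatory T-like cells were 0.229% and 0.0959% (-1.26, -2.19 to -0.33). With the 33 and 19 cells of the clustering without differing genes, that ratio was -0.75 (-1.57 to 0.06). CD8 T-like and NK-like cells were then at -0.47 and -0.27, with upper limits of 0.07 and 0.39.

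Within macrophage/monocyte-like cells, clusters were formed without the 415 genes that differed 1.5-fold or more between the libraries. With 1 library per group, a cluster mostly of 1 library may be that library, not a type. Cluster P0, led by Olr1, Thbs1, Ptgs2 and Il1b, of which Il1b encodes an inflammatory cytokine and Ptgs2 a prostaglandin synthase, held 26.9% (24.1 to 29.9%) of the class in the library labelled vector and 17.4% (14.8 to 20.3%) in the library labelled SPP1, a log2 ratio of -0.63 (-0.90 to -0.36). Cluster P5, led by Ciita, Cxcl9, Cd86 and Ccr2, held 12.1% and 8.63% (-0.48, -0.90 to -0.06). Ciita encodes the transactivator of MHC class II genes and Ccr2 a chemokine receptor of monocytes. Cluster P6, led by Fcrls, Gas6, Cbr2 and F13a1, held 4.95% and 11.2%, from 46 and 84 cells, a log2 ratio of 1.17 (0.67 to 1.67). Cluster P1, of low UMI content and led by Col3a1, Sparc and Actb, of which the first encodes the collagen abundant in the compartment, held 15.8% and 20.6% (0.38, 0.08 to 0.67). Cluster P3, led by the cell cycle genes Top2a and Mki67, held 13.6% and 16.5% (0.28, -0.05 to 0.61). The shares of P2, led by Hspa1b, Mmp13 and Gpnmb, were 15.3% and 16.2% (0.08, -0.24 to 0.40), and those of P4, led by Ccl8 and Ms4a7 among others, were 11.4% and 9.56% (-0.26, -0.66 to 0.15).

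Among the genes that the size rule named in the large compartment, Pcdh9 and Nrep differed most. The cell adhesion gene Pcdh9 was higher in the library labelled SPP1, at 17.9 and 70.5 CPM (log2 ratio 1.98, 1.92 to 2.04), as was Nrep, a gene named for neuronal regeneration, at 28.0 and 99.5 CPM (1.83, 1.78 to 1.88). Without clusters 4 and 12, these ratios were 1.17 and 0.87. Also higher were the growth factor Pdgfc (1.28, 1.22 to 1.33), the activin subunit Inhba (0.75, 0.72 to 0.77), fibronectin Fn1 (0.74, 0.73 to 0.76, at 415 and 695 CPM) and the Wnt modulator Dkk2 (0.64, 0.63 to 0.66, at 757 and 1183 CPM). The remaining genes of the higher set were Rgcc, a regulator of the cell cycle (0.92), the noncoding RNA Snhg18 (0.80), the transcriptional inhibitor Id3 (0.79), Psd3 (0.75), the retinoic acid binding protein gene Crabp1 (0.72) and the planar polarity gene Prickle1 (0.71). Without clusters 4 and 12 all 12 stayed higher, at 0.23 to 1.17, but 9 were under 1.5-fold, among them Inhba (0.56), Fn1 (0.39), Dkk2 (0.35), Id3 (0.34) and Psd3 (0.23), while Pdgfc was at 0.79. The rule gave 7 genes that were lower. These were the ferritin receptor gene Scara5 (-0.99, -1.04 to -0.94), the lipoprotein receptor gene Vldlr (-0.88), the keratin Krt14 (-0.84, -0.88 to -0.81, at 137 and 76.6 CPM), the heparan sulfate sulfatase Sulf2 (-0.77), the ErbB ligand Nrg1 (-0.75), the monocyte chemokine Ccl7 (-0.64) and the sterol synthesis gene Msmo1 (-0.62). They were at -0.73 to -0.40 without the same clusters, and 5 were under 1.5-fold. Clusters 4 and 12 held 1668 and 848 cells of the library labelled SPP1 against 63 and 64 of the other, so class sums weigh different clusters in the 2 libraries. Cluster 0, the largest, held 1572 against 2706, so the clusters left without 4 and 12 were not balanced either. Pcdh9, Nrep and Id3 are top genes of cluster 4, and Pdgfc, Inhba, Dkk2, Crabp1 and Prickle1 are top genes of cluster 12.

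Among the fixed lists in the compartment, hypoxia genes were lower in the library labelled SPP1, with a median log2 ratio of -0.21 (-0.23 to -0.16) that lay below all 10000 random lists. Of its 15 measured members 11 were lower, among them the carbonic anhydrase Car9 (-0.54) and the prolyl hydroxylases P4ha2 (-0.32) and Egln3 (-0.31). That median was -0.04 without clusters 4 and 12. Interferon gamma response genes had a median of -0.12 (-0.18 to -0.10, percentile 1.89), with Gbp2 at -0.39 and Cxcl9 at 0.46, and the class I antigen presentation list -0.12 (-0.13 to -0.07, percentile 1.39), with H2-K1 at -0.29 and Erap1 at -0.36. Without clusters 4 and 12 these medians turned to 0.18 and 0.14. Type I interferon response genes were at 0.13 (0.09 to 0.19, percentile 98.0), with 13 of 16 higher, such as Rsad2 (0.57) and Isg15 (0.44), and the median was 0.45 without the same clusters but 0.02 in thinned cells. Leaving out clusters 4 and 12 took 2516 of 10007 cells from the library labelled SPP1 and 127 of 10175 from the other. The remaining clusters then weigh more in the former by construction, among them cluster 15, led by Ifit1, Ifit3 and Isg15 (313 and 298 cells). How much of these shifts comes from that weight was not tested. NF-kB targets had a median of 0.08 (percentile 97.3), with Cxcl2 at 0.55 and Cxcl1 at 0.24, and 11 of 13 members were higher.

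The class II presentation list was at 0.07 (percentile 90.2) in the compartment, with its invariant chain gene Cd74 at 0.46, and at 0.36 without clusters 4 and 12. Proliferation genes were at -0.06 (percentile 32.7), with Rrm2 at -0.33 and Ube2c at -0.23, and glycolysis genes at -0.06 (percentile 28.7), with Eno1 at -0.20 and Tpi1 at 0.17. Both medians turned to 0.04 and 0.05 without clusters 4 and 12. TGF-beta targets were at 0.04 (percentile 90.2), with Id3 at 0.79 and Pmepa1 at 0.34, and turned to -0.05 without those clusters. The epithelial-mesenchymal and matrix list was at -0.02 (percentile 47.4), with Fn1 at 0.74 and the transcription factor Snai2 at -0.49, and dissociation stress genes at 0.04 (percentile 85.5), with Dnajb1 at 0.49 and Jund at -0.39. Chemokines were at -0.03 (percentile 23.6), with Ccl7 at -0.64 and Cxcl2 at 0.55, and checkpoint ligands at -0.06 (percentile 19.0), with Tnfsf4 at -1.10 from a level under 1 CPM. Without clusters 4 and 12 these 2 medians turned to 0.19 and 0.01. Inflammatory fibroblast genes were at 0.12 (percentile 95.9), with Pi16 at 2.05 from 1.49 and 6.14 CPM and the chemokine Ccl2 at -0.27, and contractile fibroblast genes at 0.17 (-0.03 to 0.23, percentile 92.8), with Acta2 at -0.75. Angiogenic endothelium genes were at 0.16 (-0.11 to 0.27, percentile 76.9), with Esm1 at 2.45 from 0.855 and 4.67 CPM. The epithelial identity list was at 0.43 (-0.18 to 0.64, percentile 95.2), but apart from Tjp1 its members stood under 2 CPM in the compartment, and the median was -0.21 among members with at least 100 UMIs. SPP1 receptor genes were at -0.08 (percentile 20.2). The hyaluronan receptor Cd44 stood at 1268 and 1247 CPM (-0.02), Itgav at 241 and 246 CPM (0.03, which turned to -0.05 without clusters 4 and 12), Itgb1 at -0.14, Itgb5 at -0.45 and Itgb3 at -0.74 from 4.49 and 2.69 CPM. Itga4 and Itga9 were under 1 CPM in both libraries, at -0.71 (-1.56 to 0.11) and 0.18 (-0.29 to 0.66), or -1.56 and 2.35 in thinned cells. Cd274, which encodes PD-L1, was at -0.12 (-0.20 to -0.05) and turned to 0.18 without clusters 4 and 12, and Pdcd1, which encodes PD-1, had 12 and 7 UMIs.

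**Figure D3:**
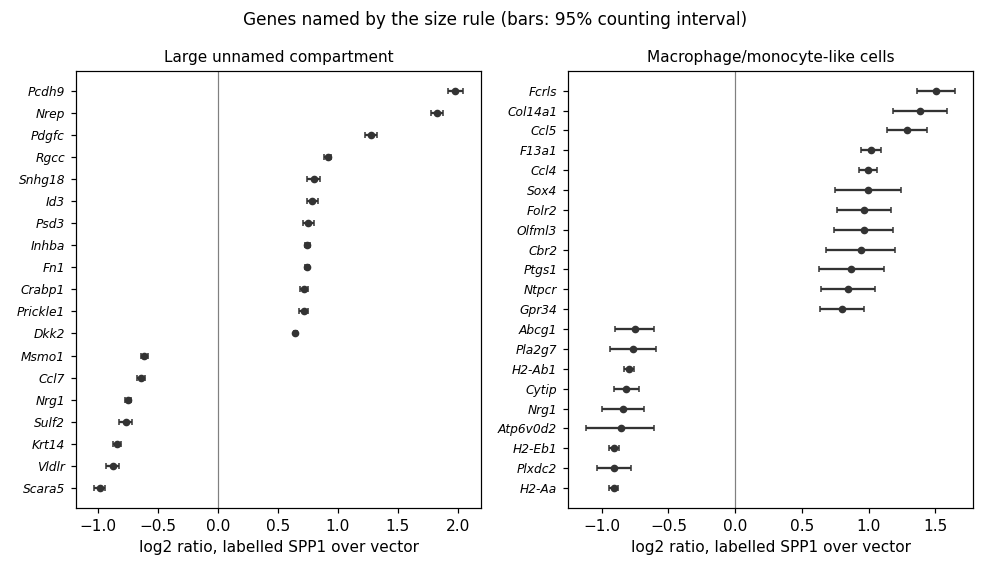
Log2 ratio of the library labelled SPP1 over the library labelled vector for the genes named by the size rule, in the large compartment (left) and in macrophage/monocyte-like cells (right). Points are ratios of CPM, bars are 95% counting intervals, and values range from Pcdh9 at 1.98 to Scara5 at -0.99 on the left and from Fcrls to H2-Aa at -0.91 on the right.

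In macrophage/monocyte-like cells, MHC class II genes were lower in the library labelled SPP1 and genes that lead cluster P6 were higher. H2-Aa was at 3370 and 1792 CPM (log2 ratio -0.91, -0.95 to -0.88), H2-Eb1 at -0.91 (-0.94 to -0.87) and H2-Ab1 at -0.79 (-0.83 to -0.75), all 3 encoding class II chains. The scavenger-type receptor gene Fcrls was at 85.3 and 242 CPM (1.36 to 1.65 on the log2 scale), the coagulation factor F13a1 at 348 and 703 CPM (1.02, 0.94 to 1.09), the folate receptor gene Folr2 at 0.96 (0.76 to 1.16), Cbr2 at 0.94 (0.68 to 1.20) and Gpr34 at 0.80 (0.63 to 0.97). Of these, Fcrls, F13a1, Cbr2 and Gpr34 lead cluster P6, which held 11.2% of the class in the library labelled SPP1 and 4.95% in the other. The chemokine Ccl4 was at 458 and 914 CPM (1.00, 0.93 to 1.06). Ccl5 was at 80.9 and 197 CPM (1.29, 1.14 to 1.44), but 3 cells held 45.7% of its UMIs in the library labelled SPP1, and the ratio was 0.64 in cells thinned to a fixed number of UMIs and 0.38 as a mean over cells. Also higher were collagen XIV, Col14a1 (1.38, 1.18 to 1.58), which stood at 1.87 and 2.25 CPM in the compartment, Sox4 (0.99, 0.74 to 1.24), Olfml3 (0.96), Ntpcr (0.84) and the cyclooxygenase gene Ptgs1 (0.87, but 0.08 in thinned cells). Col14a1 is a top gene of the fibroblast-like cluster. With the differing genes kept, it is also a top gene of a macrophage/monocyte-like cluster of 53 and 150 cells. Sox4 stood at 353 and 356 CPM in the compartment, whose collagen Col3a1 was at 254 and 354 CPM in macrophage/monocyte-like cells. Also lower were Plxdc2 (-0.91, -1.04 to -0.78), the proton pump subunit gene Atp6v0d2 (-0.86, -1.12 to -0.61, but -0.31 with doublets kept), a top gene of cluster P2, the ErbB ligand Nrg1 (-0.84) and Cytip (-0.81), top genes of cluster P0, the phospholipase gene Pla2g7 (-0.77, but -0.44 in thinned cells) and the cholesterol exporter gene Abcg1 (-0.75).

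The class II presentation list had a median of -0.69 (-0.76 to -0.57) in macrophage/monocyte-like cells, below all 10000 random lists, and 8 of 8 measured members were lower, including the transactivator Ciita at -0.81 (-1.11 to -0.51), a top gene of cluster P5. The neutrophil suppression list was at -0.28 (-0.32 to -0.14), also below all random lists. Its members Il1b (-0.61), a top gene of cluster P0, and Nos2 (-0.77) were lower, and the chemokines Ccl4 (1.00) and Ccl3 (0.58) higher. Interferon gamma response genes were at -0.22 (-0.27 to -0.15, percentile 0.36), with Gbp5 at -0.76, and at -0.43 in thinned cells. Type I interferon response genes were at 0.40 (0.24 to 0.55), above all random lists, with 13 of 16 higher, such as Isg15 (0.94) and Cmpk2 (0.84). That median was 0.06 in thinned cells and 0.09 as a mean over cells. Chemokines were at 0.20 (0.13 to 0.25, percentile 99.9), led by Ccl5, Ccl4 and Ccl3. The T cell gene Cd3e had 1 and 13 UMIs in this class, the 13 of them in 3 cells, and 3 cells of the library labelled SPP1 held 80.8% of 26 Gzmb UMIs. Proliferation genes were at 0.32 (0.20 to 0.39, percentile 99.99), with 16 of 17 higher, such as Tyms (0.73) and Cenpf (0.65), and 9 with an interval above 0. Transcripts of the compartment, of which 26.7% and 25.3% of cells were cycling, were also higher in these cells: Col3a1 at 0.48, Sox9 at 0.40 and Hmga2 at 0.33.

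Checkpoint ligands were at -0.17 (-0.27 to -0.02, percentile 2.72) in the same cells, with Pdcd1lg2 at -0.64 (-1.02 to -0.28), Cd80 at -0.38 and Cd274 at 206 and 163 CPM (-0.33, -0.46 to -0.21). Class I presentation was at -0.14 (percentile 5.04), with H2-K1 at -0.29 and the proteasome subunit Psmb10 at 0.40. The alternatively activated macrophage list was at -0.17 (-0.37 to 0.03, percentile 1.63). Its members went both ways, with Folr2 at 0.96 and Chil3 at -0.74. Retnla was at -3.12 from 100 and 9 UMIs, of which 3 cells held 79.0% and 88.9%. The inflammatory macrophage list was at -0.12 (-0.21 to 0.04, percentile 6.77), with Il1b at -0.61, and at -0.13 with Il12b at its bound, since that gene had 23 UMIs in 1 cell of the library labelled vector and 0 in the other, at least 5.98-fold lower against the floor of 3 counts. The lipid-associated list was at 0.03 (percentile 71.9), with the lipid carrier Apoe at 1994 and 3328 CPM (0.74) and the fatty acid handling genes Cd36 (-0.68), Lpl (-0.65) and Fabp5 (-0.64) lower. TGF-beta targets were at 0.12 (-0.03 to 0.39, percentile 92.6), with Pmepa1 at 0.47, and dissociation stress genes at 0.03 (percentile 68.6), with Jun at 0.40 and Dusp1 at -0.35. NF-kB targets were at 0.04 (percentile 77.9), with Ier3 at 0.29 and Tnfaip2 at -0.48. Hypoxia genes were at -0.03 (percentile 50.5), with Ndrg1 at -0.41 and Hk2 at 0.28, and glycolysis genes at 0.02 (percentile 77.4), with Hk1 at 0.45 and Pfkp at -0.26. In thinned cells these 2 medians were -0.28 and -0.06. SPP1 receptor genes were at 0.07 (percentile 86.4), with Cd44 at -0.12, Itgav at 0.11, Itgb1 at 0.11, Itga5 at 0.20, Itga4 at -0.11 (-0.28 to 0.05) and Itga9 at 0.03 (-0.16 to 0.21). Itgb3 had 12 and 3 UMIs and Pdcd1 1 and 3.

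**Figure D4:**
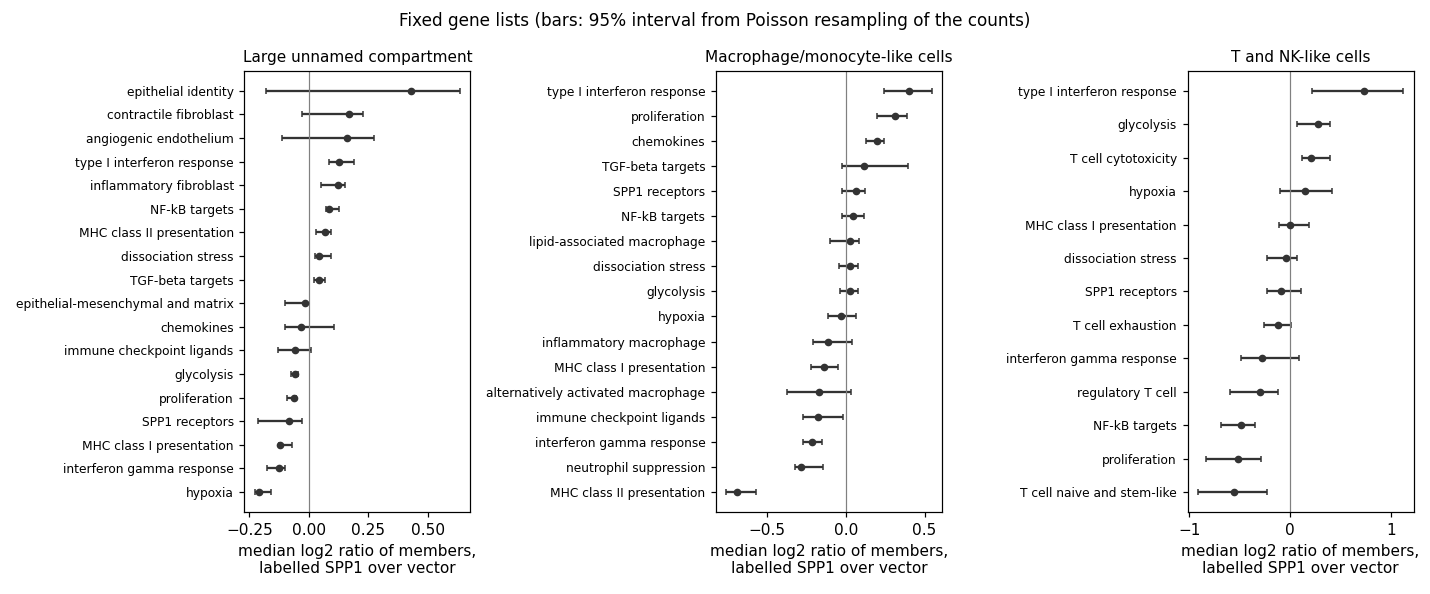
Median log2 ratio of the library labelled SPP1 over the library labelled vector for each described gene list in the large compartment, macrophage/monocyte-like cells and T and NK-like cells, with 95% intervals from Poisson resampling of the counts. The class II presentation list stands at -0.69 in macrophage/monocyte-like cells, and the scale of the horizontal axis differs between panels.

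In T and NK-like cells, the granzyme genes Gzmd, Gzme, Gzmf and Gzmg were higher in the library labelled SPP1 and genes of regulatory T cells were lower, on few cells in both cases. Gzmb, picked after its values were seen, was at 2036 and 1979 CPM (-0.04, -0.16 to 0.07). Gzmg was at 143 and 1512 CPM (log2 ratio 3.40, 3.11 to 3.71), Gzmf at 1.83 (1.72 to 1.95), Gzmd at 1.75 (1.61 to 1.89) and Gzme at 1.65 (1.43 to 1.87), proteases of cytotoxic granules. The 3 highest cells held 89.1%, 92.8%, 85.0% and 75.0% of these UMIs in the library labelled SPP1. Without the 3 highest cells of each library Gzmf turned to -0.59, and Gzmd, Gzme and Gzmg were at 0.59, 1.21 and 2.95. In thinned cells Gzmg, Gzmf, Gzmd and Gzme were at 2.12, 1.04, 0.87 and 1.90. The serpin gene Serpinb9b (1.57, 1.15 to 1.99) and Basp1 (1.76, 1.24 to 2.30) turned to -0.06 and -0.19 without such cells. In thinned cells they were at 0.16 and -1.46, and Serpinb9b was at 0.55 as a mean over cells. Gzmd, Gzme and Ncr1 are top genes of the NK-like cluster. Ctsg, a protease gene, had 0 UMIs in the library labelled vector and 107 in the library labelled SPP1, at least 51.7-fold higher against a floor of 3 counts, but 6 cells held them and 1 of these held 78. Lower genes were Frmd5 (-2.72, -3.45 to -2.07), Itgb8 (-1.35, and -2.10 without the 3 highest cells of each library), which encodes an integrin chain that activates TGF-beta, and Il2ra (-1.12, -1.59 to -0.67, but -0.65 as a mean over cells and -0.56 in thinned cells), the interleukin 2 receptor gene. Further lower genes were Zfp36l2 (-1.38), the growth factor Areg (-1.38, but -0.61 as a mean over cells and -0.70 in thinned cells), the NK receptor gene Ncr1 (-1.22), the topoisomerase Top2a (-0.96, but -0.24 as a mean over cells) and the phosphatase gene Dusp1 (-0.85). Frmd5, Itgb8, Il2ra and Areg, and Foxp3 and Il10 named below, are top genes of the regulatory T-like cluster, which held 32 and 13 cells. Top2a is a top gene of a CD8 T-like cluster of 11 and 6 cells, and Lef1, named below, of a cluster without a name of 24 and 9.

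The cytotoxicity list was at 0.20 (0.12 to 0.40, percentile 99.7) in T and NK-like cells, with 9 of 14 members higher and Tnf at -1.09 (-2.22 to -0.08), and at 0.42 in thinned cells. The naive and stem-like list was at -0.56 (-0.91 to -0.23, percentile 0.58), with 8 of 8 lower, such as Lef1 (-1.31), but only 3 with an interval below 0. The regulatory T cell list was at -0.30 (-0.60 to -0.12, percentile 3.86), with 8 of 9 lower, such as Foxp3 (-1.46, -3.04 to -0.14) and Il10 (-1.73). Il10 had 82 and 17 UMIs, of which the 3 highest cells held 70.7% and 82.4%. The exhaustion list was at -0.12 (-0.26 to 0.01, percentile 28.2), with Cd160 at -1.69 and Rgs16 at -0.81, but 0.02 as a mean over cells and 0.03 in thinned cells, and Pdcd1 itself at 187 and 184 CPM (-0.02, -0.41 to 0.36). Proliferation genes were at -0.51 (-0.84 to -0.29, percentile 0.06), with Mki67 at -1.02, and the median was -0.18 as a mean over cells. NF-kB targets were at -0.49 (-0.68 to -0.35, percentile 0.01), with Nfkb2 at -1.72, and at -0.27 as a mean over cells. Its member Cxcl2, at -3.77, had 84.8% of its UMIs in 3 cells of the library labelled vector. Macrophage genes were also lower in this class, with Lyz2 at 122 and 10 UMIs, 82.8% of the 122 in 3 cells, Il1b at 101 and 1 and Cd14 at 48 and 2. Glycolysis genes were at 0.27 (0.07 to 0.39, percentile 99.9), with Ldha at 0.41 and Tpi1 at 0.62, and hypoxia genes at 0.15 (-0.10 to 0.42, percentile 93.4), with Ero1a at 0.68. In thinned cells these 2 medians were 0.49 and 0.42. Type I interferon response genes were at 0.73 (0.22 to 1.12, percentile 99.9), where 6 members were measured and each single interval included 0, as for Rsad2 (0.91, -0.39 to 2.26). Interferon gamma response genes were at -0.28 (-0.49 to 0.08, percentile 10.9), with Gbp2 at -0.67 (-1.90 to 0.46), and class I presentation at -0.00 (percentile 61.9), with Psmb8 at 0.40. Dissociation stress genes were at -0.04 (percentile 62.7), with Hspa1a at 2.03 and Fos at -0.70. Hspa1a had 16 and 45 UMIs, of which the 3 highest cells held 75.0% and 77.8%. SPP1 receptor genes were at -0.09 (-0.23 to 0.11, percentile 36.9), with Cd44 at -0.08, Itgav at -0.11, Itgb1 at 0.03, Itgb3 at -0.37 and Itga4 at 0.35 (0.01 to 0.68). Cd274 was at -0.03 (-0.52 to 0.45), and Itga9 had 0 UMIs in both libraries.

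Cycling cells, taken as those with a UMI of Mki67 or Top2a after thinning to 1000 UMIs, made up 26.7% (25.9 to 27.6%) of the compartment in the library labelled vector and 25.3% (24.5 to 26.2%) in the library labelled SPP1, a log2 ratio of -0.08 (-0.14 to -0.01). The unthinned shares there were 58.0% and 57.9%. Macrophage/monocyte-like cells cycled at 14.8% (12.5 to 17.4%) and 16.6% (13.9 to 19.6%), and T and NK-like cells at 17.7% (12.4 to 24.0%) and 15.3% (9.18 to 23.4%), with log2 ratios of 0.16 (-0.17 to 0.49) and -0.21 (-0.98 to 0.57). Unthinned, these were 35.4% and 39.6%, and 34.7% and 34.5%. Thinning left out 22 and 31 cells of the compartment, 60 and 66 macrophage/monocyte-like cells and 9 and 8 T and NK-like cells.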

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

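All tests in this part were chosen after the patterns had been seen, and only the bounds of the chromosome test were written before its value. The references for free Spp1 RNA, and the reasons to set some of them aside, were picked after their values had been seen. The results that follow were picked out because a class of cells stood higher in the library labelled SPP1 and another stood lower. The class II presentation list had a median log2 ratio of 0.069 in the compartment and -0.69 in macrophage/monocyte-like cells. The proliferation list was at 0.32 in macrophage/monocyte-like cells and -0.51 in T and NK-like cells. Spp1 was at 1.55 in T and NK-like cells and -1.75 in fibroblast-like cells. The difference between the classes was not tested in any of these.

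Spp1 was not higher in the compartment of the library labelled SPP1 taken whole. Swapped labels, with the construct counted at mouse Spp1, would give a log2 ratio of -1 or lower, and it was -0.073 (-0.10 to -0.04), but free RNA keeps them open: with the level of cluster 4, the lowest in the compartment, taken off the library labelled SPP1 alone, it could be as low as -0.54, or -1.17 in thinned cells (-0.68 at point values), and -0.18 and -0.70 without clusters 4 and 12. Free RNA that hides a raised level stays open too: taken off the library labelled vector alone, it allowed at most 0.34, but 0.62 without clusters 4 and 12, between the bounds of 0.58 and 1. References that were tried and decide nothing were cluster 0 (-1.02 and 0.55), whose level lies above that of cluster 4, and, with upper bounds over 50% of the compartment's level, regulatory T-like cells (1.68, or -1.60 taken off both libraries) and 61 thinned cells of cluster 4 in the library labelled vector (5.42). A construct whose transcript is not counted at mouse Spp1 remains possible, since 0 features in the tables belonged to a vector or another species.

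Clusters 4 and 12 held almost only cells of the library labelled SPP1. A shift of the whole library stays open: the 12 genes named as higher had a median log2 ratio of 0.48 without these clusters and 0.77 with them, between the bounds of 0.58 and 0.2, and they were picked with these clusters included. A clone of the injected pool with its own chromosome copy numbers stays open. The largest chromosome median was 0.198 (0.164 to 0.226) on chromosome 18, against -0.182 on chromosome 19 in cluster 5, a control. Chromosome 18 was at 0.24 in cluster 4 alone and 0.115 (0.086 to 0.141) in cluster 12 alone. Compared with cluster 3 only, which was closer in depth (medians of 18039 and 19674 UMIs), cluster 12 was at 0.2002 (0.1574 to 0.2337) there. The value of 0.198 lay just under the bound of 0.2 written beforehand for a negative result. The demand that its interval lie there too was added after the value was seen. An effect of the construct could not be told from a clone with 1 library per group: 12.9% of compartment cells had a UMI of Magea9, a top gene of both clusters, in the library labelled SPP1 (36.6% in these clusters and 4.89% in the others), and 3 of 10175 in the other library, with 0 of its 127 cells in these clusters.

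The compartment lacked Krt8, Krt18, Krt19 and most of the epithelial list, although it held Krt14 at 137 and 76.6 CPM and Tjp1 at up to 183 CPM. Host fibroblasts as its source would carry Xist as the fibroblast-like cells do, but it held at most 0.547% of their level, 3.01 and 2.72 CPM against 549 and 825. A table that does not count epithelial genes is unlikely for the list as a whole, since 6 of its 14 genes reached 10 CPM in another class, although Krt8, Krt18 and Krt19 did so in none. Cells other than the labelled line were not ruled out: 1 of 15 tumour markers, Msln at 25.2 CPM, reached 10 CPM in the compartment, and no reference profile of the line was used here.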

How the results depend on the processing

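Settings described as added were chosen after the data had been examined. A value counts as reversed only where its sign turned and its reported interval excluded 0, and other values outside the interval count as moved, also where the sign turned. Among log2 ratios of genes, 387 values under settings chosen before the data were examined stayed within their interval, 88 moved and 4 reversed, and under added ones 70, 31 and 7. Among list medians the earlier settings left 334 within their interval and moved 48, with none reversed, and the added ones gave 6, 7 and 5. Among class shares they were 62, 8 and 2, and for the added ones 7 stayed and 2 moved. T and NK sub-class shares stayed in 25 earlier and 7 added values. Share log2 ratios ranged from -0.64 to -0.30 for T and NK-like cells, -0.89 to -0.49 for dendritic cell-like cells, -0.33 to 0.07 for macrophage/monocyte-like cells, 0.10 to 0.41 for fibroblast-like cells, 0.19 to 0.63 for endothelial-like cells, -0.64 to -0.39 for cluster P0 and 0.94 to 1.43 for cluster P6. No value was given for clusters P5 and P6 at resolution 0.5, regulatory T-like cells at resolution 2.0, CD8 T-like cells when cells were thinned before clustering and unnamed T and NK-like cells under the stricter filter. No paired analysis was possible because there was 1 library per group. Of the 3 classes whose genes were ranked, T and NK-like cells had the fewest UMIs, 763128 and 526419 against 142656731 and 139717338 in the compartment, and the dendritic, stromal and endothelial classes had fewer still. The cause was not tested for any value below, except that changed denominators move shares by construction.

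Without the 3 highest cells of each library (added), Spp1 was at -0.16 over all cells, 0.24 in macrophage/monocyte-like, 0.072 in T and NK-like, -2.43 in dendritic cell-like and -2.28 in fibroblast-like cells, and in T and NK-like cells Gzmf reversed to -0.59, Basp1 to -0.19 and Serpinb9b to -0.059. Without clusters 4 and 12 (added), Spp1 was at 0.10 over all cells and 0.21 in the compartment, Itgav at -0.046 and Cd274 at 0.18. Compartment list medians were then type I interferon 0.45, interferon gamma 0.18, class I 0.14, class II 0.36, checkpoint ligands 0.010, chemokines 0.19, hypoxia -0.035, glycolysis 0.048, proliferation 0.039, inflammatory fibroblast 0.19, dissociation stress 0.0047 and TGF-beta targets -0.050.

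In cells thinned to 1000 UMIs, Spp1 was at -0.094 over all cells, 0.0041 in the compartment, 1.11 in T and NK-like and -1.88 in fibroblast-like cells, Basp1 reversed to -1.46 in T and NK-like cells and Itgav to -0.020 in the compartment. Compartment lists were type I interferon 0.020, interferon gamma -0.23, class II 0.14, checkpoint ligands 0.019, NF-kB 0.044, hypoxia -0.15, glycolysis -0.034, inflammatory fibroblast 0.18 and TGF-beta 0.013. Macrophage/monocyte-like lists were SPP1 receptors 0.17, type I interferon 0.064, interferon gamma -0.43, class I -0.24, inflammatory macrophage -0.22, hypoxia -0.28, glycolysis -0.061 and neutrophil suppression -0.33. T and NK-like lists were cytotoxicity 0.42, exhaustion 0.034, hypoxia 0.42 and glycolysis 0.49.

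As a mean over cells, Spp1 was at -0.078 over all cells, -0.031 in the compartment, 0.30 in macrophage/monocyte-like, 1.12 in T and NK-like and -1.89 in fibroblast-like cells. Compartment lists were class I -0.14, NF-kB 0.058, inflammatory fibroblast 0.033 and dissociation stress 0.0081. Macrophage/monocyte-like lists were type I interferon 0.089, interferon gamma -0.31, inflammatory macrophage -0.27 and chemokines 0.27, and T and NK-like lists exhaustion 0.022, NF-kB -0.27 and proliferation -0.18. With median-of-ratios scaling, Spp1 was at -0.21 over all cells, -0.10 in the compartment, 0.17 in macrophage/monocyte-like and -1.91 in fibroblast-like cells, and Itgav reversed to -0.0035 in the compartment. Its lists there were class I -0.15, NF-kB 0.054, hypoxia -0.24, glycolysis -0.090, dissociation stress 0.012 and TGF-beta 0.012. This scaling moved all fibroblast-like ratios by -0.17 and endothelial-like ratios by 0.11. With TMM, class I was at -0.14 and NF-kB at 0.071 in the compartment.

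With list members of at least 1 UMI in each library, compartment medians were SPP1 receptors -0.024, class II 0.025 and angiogenic endothelium 0.30, and the lipid-associated median in macrophage/monocyte-like cells was 0.091. With at least 100 UMIs they were SPP1 receptors -0.024, class II 0.025 and epithelial identity -0.21, and T and NK-like proliferation was -0.84.

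Macrophage/monocyte-like shares reversed to 0.037 outside the compartment and 0.072 among immune cells, where T and NK-like cells were at -0.30. The compartment's share ratio was 0.041 with another seed (added), 0.042 with doublets kept and 0.041 with each library on its own. That of low-UMI cells was -0.033 with another seed (added), -0.042 with doublets kept, -0.031 with each library on its own, -0.037 with the looser filter, -0.019 at resolution 0.5 and -0.027 at resolution 2.0. Cluster P2 was at 0.44 at resolution 0.5, and cycling in the compartment at -0.0021 unthinned.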

Other observations

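The pairs of list and class in this part were set aside after their values had been seen, and none was recomputed under the alternatives. In macrophage/monocyte-like cells, genes of the cytotoxicity list were higher in the library labelled SPP1, with a median log2 ratio of 1.00 (0.61 to 1.33) and 7 of 7 measured members higher. These include the chemokines Ccl3, Ccl4 and Ccl5, and genes of cytotoxic lymphocytes with few UMIs, Gzmb (4 and 26) and Nkg7 (8 and 16). In the library labelled SPP1, 3 cells held 80.8% and 93.8% of these, and 3 cells held the 13 UMIs of the T cell gene Cd3e, which had 1 in the other. Epithelial-mesenchymal and matrix genes were at 0.37 (0.12 to 0.45, percentile 99.99) there with 12 of 16 higher, contractile fibroblast genes at 0.59 (0.11 to 1.02) and inflammatory fibroblast genes at 0.21. Angiogenic endothelium genes were at -0.59 (-0.95 to 0.05), exhaustion genes at -0.06, naive and stem-like genes at 0.10 and epithelial identity genes at -0.12. The regulatory T cell list had fewer than 3 measured members in these cells.

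In T and NK-like cells, class II presentation genes were at -3.16 (-3.85 to -2.37) with 5 of 5 lower. H2-Aa had 150 and 7 UMIs there, and 3 cells held 82.0% of those in the library labelled vector. The alternatively activated macrophage list was at -1.60 (-2.27 to -0.87), the inflammatory macrophage list at -0.81 (-1.32 to -0.13), the neutrophil suppression list at -0.53 (-0.85 to -0.09) and TGF-beta targets at -0.28 (-0.76 to -0.11). The macrophage gene Lyz2 had 82.8% of its UMIs in 3 cells of the library labelled vector. Chemokines were at 0.05, epithelial identity at 0.14, epithelial-mesenchymal and matrix at -0.11, checkpoint ligands at -0.05, inflammatory fibroblast at 0.11 and lipid-associated macrophage at -0.04. The angiogenic endothelium and contractile fibroblast lists had fewer than 3 measured members there.

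In the compartment, the naive and stem-like list was at -0.18 (-0.25 to -0.10), the regulatory T cell list at -0.27 (-0.40 to 0.25), cytotoxicity at 0.19, exhaustion at 0.13, alternatively activated macrophage at 0.07, inflammatory macrophage at -0.07, lipid-associated macrophage at 0.01 and neutrophil suppression at -0.05. When the compartment was clustered without the 861 genes that differed between the libraries, a cluster of 84 and 1435 cells remained, with 1362 of its cells from cluster 4. It held 1332 of the 2516 cells of clusters 4 and 12 in the library labelled SPP1. Another 426 and 375 of these lay in clusters shared by the libraries, of 1387 and 1360 and of 1240 and 1128 cells. The largest cluster of that clustering was unbalanced the other way, with 2208 cells of the library labelled vector and 1090 of the library labelled SPP1.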
